A study of Mus musculus with 6 samples.

How the data were processed

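Small RNA was measured in purified primordial germ cells of male mouse embryos at embryonic day 13.5, in 6 libraries. Per the labels, 3 libraries came from cells exposed to ionizing radiation (IR) and 3 from untreated control cells. Per the labels' protocols, RNA of 18 to 50 nt was size-selected and libraries were made with the NEBNext small RNA kit. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate animals, so p-values measure the spread between these libraries, which may be technical.

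The deposited values are read counts: each line of a file gives a read sequence, its count of copies in the library, its strand, the number of places it maps to and 1 of those places. Per the submitters' processing notes the genome build was mm10. The aligner, adapter trimming, allowed mismatches and any filter on other RNA classes are not given in the sources used here. The number of mapped places, the other deposited value, was checked against the lines and equalled the number of lines of the sequence for every sequence of every library. Positions are on piRNA cluster transcripts, not on chromosomes, and are printed here counted from 1. Of 68996 positions listed, 5949 carried more than 1 sequence, so reads that differ in some bases were placed together. Reads ranged from 20 to 85 nt. A file holds only the reads that mapped to cluster transcripts, so its total is not the depth of the library, and the library depth was not used here.

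Reads were counted with their copies, and the copies of a sequence entered once per library however many places it mapped to. A locus was a piRNA gene, all transcripts of 1 name with the last number removed. The design fixed before the data were examined had foreseen chromosome positions, merged within 10 kb, and reads mapping once in the genome. Transcript positions cannot be merged so, and the main locus count was therefore of reads whose places all lay in 1 piRNA gene. Reads fell on 214 piRNA genes, of which 114 are named after a gene and 100 after a chromosome band. Of the former, 113 were found in GENCODE vM21, an annotation of the same build, some of them by an older symbol. No coordinates are given for genes named after a band.

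Counts per locus, per sequence and per read length were compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM normalization, filterByExpr, the quasi-likelihood F-test and Benjamini-Hochberg adjustment, with adjusted p under 0.05 as the threshold. For read lengths the library size was the total of the file, without TMM. Standard errors (SE) are the log2 fold change divided by the square root of F. CPM values are counts scaled by the effective library size of the comparison. Composition measures were compared by exact two-sided permutation over the 20 regroupings of the 6 libraries, whose smallest p is 0.1, so that none of these tests can reach 0.05. For equal depth, each library was thinned to 7788 reads in 20 seeded draws. Ping-pong pairs were opposite-strand reads of 24 to 32 nt whose 5' ends overlapped by 1 to 20 nt, weighted by copies divided by mapped places. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

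The fits were tested on simulated counts with the means, library sizes and common dispersion of these libraries. Because few features passed the filter, 20 of the 103 loci, 24 of the 124 sequences and 4 of the 29 lengths were changed in each of 20 draws. Among loci, 52% of 2-fold and 84.5% of 4-fold changes were recovered, with 4.55% false calls. Among sequences, 17.9% and 72.9% were recovered, with 2.24% false calls. Among lengths outside the 8 most abundant, 77.5% of 1.5-fold and 100% of 2-fold changes were recovered, with 4.05% false calls. That setting was chosen after 2-fold and 4-fold changes placed on any length had given 36.1% false calls: lengths are shares of 1 total, and a large change in an abundant length shifts the others. For counts by source RNA, run on 114 features, 42.5% of 2-fold and 83.5% of 4-fold changes were recovered, with 3.82% false calls. Libraries of the same group differed by more than sampling noise (largest chi-square p = 1.87e-09 over loci), so none was taken for a repeated deposit of another. That check does not show that the libraries came from separate samples.

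Read sequences were matched exactly and in sense to GENCODE vM21 transcripts, and to 4.5SH RNA and tRNA sequences written from general knowledge because the annotation lacks them. This matching, and the counts by source RNA built on it, were chosen after the data were seen. A match says that a read has the sequence of that RNA, not that it was made there, since the read was also placed on a cluster transcript. The sequences of the cluster transcripts were not compared, so a matched read may differ from them in some bases. Reads that differ from the reference in 1 base stay unmatched.

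The rule for naming features was fixed before the data were examined. It takes loci past the threshold (up to 15 per direction by fold change), the 10 loci with the highest mean CPM, tested loci of the fixed gene lists, sequences past the threshold (the 5 smallest p per direction) and the 5 most abundant sequences, and all read lengths past the threshold. Lists fixed in advance covered p53 targets, DNA repair, piRNA pathway, germ cell and pluripotency, meiosis, apoptosis and histone genes, markers of Sertoli, Leydig, endothelial and blood cells, and 23 small RNA sequences matched by their first 15 nt. Set tests (camera and fry) were planned for lists with at least 3 tested loci, and no list had that many. Alternatives were DESeq2 1.42.0, other normalizations, filters, read classes and lengths, the replicate number as a block, and leaving out each library. Intervals are exact (Clopper-Pearson, 95%) and, like the 3-count floors, cover counting error only, since the reads carry no molecular identifiers here.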

Results

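Purified primordial germ cells of fetal male mice, the precursors of sperm, were profiled by small RNA sequencing with ionizing radiation (IR) and without it, with 3 libraries per group. The reads used are those that map to piRNA cluster transcripts, the precursors of PIWI-interacting RNAs, which silence transposons in the germ line. The control libraries held 10066, 8037 and 10814 such reads, of 5588, 4110 and 5809 distinct sequences. The IR libraries held 11280, 11278 and 7788 reads, of 6415, 6336 and 4564 distinct sequences. A count of 3 reads made up between 0.0266% and 0.0385% of such reads in a library. The log2 total differed by 0.060 between groups (exact permutation p = 0.6, two-sided), and as each file holds part of a library, this does not measure piRNA abundance.

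Many of the reads placed on cluster transcripts had the sequence of structured RNAs. Reads of 4.5SH RNA, an abundant rodent small RNA related to the B1 repeat, made up 22.7% ± 1.67 of control and 23.1% ± 0.401 of IR reads (SD, n = 3). Small nuclear RNA took 7.91% ± 1.66 and 8.57% ± 1.63, and small nucleolar RNA 3.24% ± 1.77 and 4.57% ± 0.511. Fragments of tRNA took 4.09% ± 0.684 and 3.09% ± 1.29, and microRNA 2.66% ± 0.322 and 2.70% ± 0.386. Structured RNAs together accounted for 41.2% ± 3.75 of control and 43.2% ± 0.634 of IR reads (exact permutation p = 0.4). These shares were computed after the data were seen.

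The first comparison asked which piRNA genes gave more or fewer reads after irradiation. Of 103 tested, 4 were higher and 4 lower in IR. With strands counted apart 7 were higher and 3 lower, and with all reads, copies divided by mapped places, 4 were higher and 8 lower. pi-Zmat3 rose 4.04-fold, from 669 ± 151 to 2807 ± 185 CPM (SD, n = 3; log2 fold change 2.01, SE 0.34, adjusted p = 0.00249, edgeR). Zmat3, a p53 target that encodes a zinc finger RNA-binding protein, lies on the minus strand of chromosome 3, 32334792 to 32366014 (mm10). The reads of pi-Zmat3 numbered 6, 3 and 6 in the control and 26, 24 and 18 in the IR libraries, and 82 distinct sequences made up these 83 reads. Of its IR reads, 41 matched Zmat3 exons exactly and in sense, 35 of them in the 3' UTR and 6 in the coding sequence. pi-Zmat3 passed the threshold in each of the 16 alternatives in which it was tested, which do not include reads of 24 to 32 nt or of 20 to 28 nt alone.

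pi-Tfcp2l1, at the gene of a transcription factor of pluripotent cells (chromosome 1, 118627945 to 118685168, plus strand), rose from 8414 ± 1506 to 31203 ± 10075 CPM (log2 fold change 1.89, SE 0.27, adjusted p = 0.000705, edgeR). Reads with the sequence of U1 small nuclear RNA made up 83.5% of its reads. Without reads of structured RNAs its log2 fold change was 0.62 (SE 0.34, adjusted p = 0.298, edgeR), with adjusted p from 4.62e-10 to 0.336 over its 17 alternatives.

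pi-Foxo3, at the gene of a forkhead transcription factor (chromosome 10, 42181841 to 42276755, minus strand), rose from 1313 ± 586 to 3311 ± 244 CPM (log2 fold change 1.28, SE 0.34, adjusted p = 0.0371, edgeR), with 107 distinct sequences among 110 reads. It was no longer past the threshold with DESeq2 (0.114), with the replicate block (0.107), or without control replicate 2 (0.0898), IR replicate 1 (0.0947), IR replicate 2 (0.166) or IR replicate 3 (0.195). Its adjusted p ranged from 0.0125 to 0.195 over the alternatives. The locus 3-qA2-617 rose by 1.07 on the log2 scale (SE 0.23, adjusted p = 0.0129, edgeR), with 391 distinct sequences among 407 reads. Its call was lost without control replicate 2 (0.0898), IR replicate 1 (0.0797) or IR replicate 2 (0.0634), in a range from 0.00422 to 0.0898 over the alternatives. On reads of 24 to 32 nt its log2 fold change was larger, 1.38 (SE 0.34), and not past the threshold (adjusted p = 0.0596, edgeR).

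Among the loci that fell, 9-qF4-150 decreased by 1.77 on the log2 scale, from 18762 ± 1865 to 5592 ± 1552 CPM (SE 0.24, adjusted p = 0.000705, edgeR). The 21-nt sequence CCTTTAATCTCGACACTTGGA gave 83.3% of its reads, 360 in the control and 95 in the IR libraries. 9-qF4-150 passed the threshold in each of its 17 alternatives, which do not include reads of 24 to 32 nt alone. Only 3.66% of its reads had that size. 15-qD1-4001, 9-qC-10667 and pi-Phf20 fell by 0.92 (SE 0.22), 0.87 (SE 0.20) and 0.82 (SE 0.19), with adjusted p of 0.0179, 0.0165 and 0.0179 (edgeR). Phf20 encodes a chromatin reader protein and lies on the plus strand of chromosome 2, 156196466 to 156309952. A tRNA-Gly fragment gave 49.7% of the reads of 9-qC-10667, and a tRNA-Lys fragment 29.2% of those of 15-qD1-4001. Without reads of structured RNAs the log2 fold change of 9-qC-10667 was -0.27 (adjusted p = 0.496, range over alternatives 0.00179 to 0.496). That of 15-qD1-4001 was then -0.30 (adjusted p = 0.460, range 0.00420 to 0.854), and on reads of 24 to 32 nt it was 0.16.

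These calls also depended on single libraries. 9-qC-10667 was no longer past the threshold without control replicate 2 (adjusted p = 0.0898, edgeR), IR replicate 1 (0.0797) or IR replicate 2 (0.0634). 15-qD1-4001 lost its call without control replicate 2 (0.0898), IR replicate 1 (0.0797), IR replicate 2 (0.0838) or IR replicate 3 (0.0536). pi-Phf20 lost it without control replicate 2 (0.0898), IR replicate 1 (0.128), IR replicate 2 (0.0634) or IR replicate 3 (0.0536), and its adjusted p ranged from 0.00236 to 0.132 over the alternatives. With reads of 1 mapped place, 15-qD1-4001, 9-qC-10667 and pi-Phf20 had adjusted p of 0.0541, 0.128 and 0.132, and on reads of 24 to 32 nt pi-Phf20 had 0.0845 (edgeR). The count of 8 loci became 4 without control replicate 2, 15 without control replicate 3, 3 without IR replicate 1, 3 without IR replicate 2 and 5 without IR replicate 3.

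**Figure D1:**
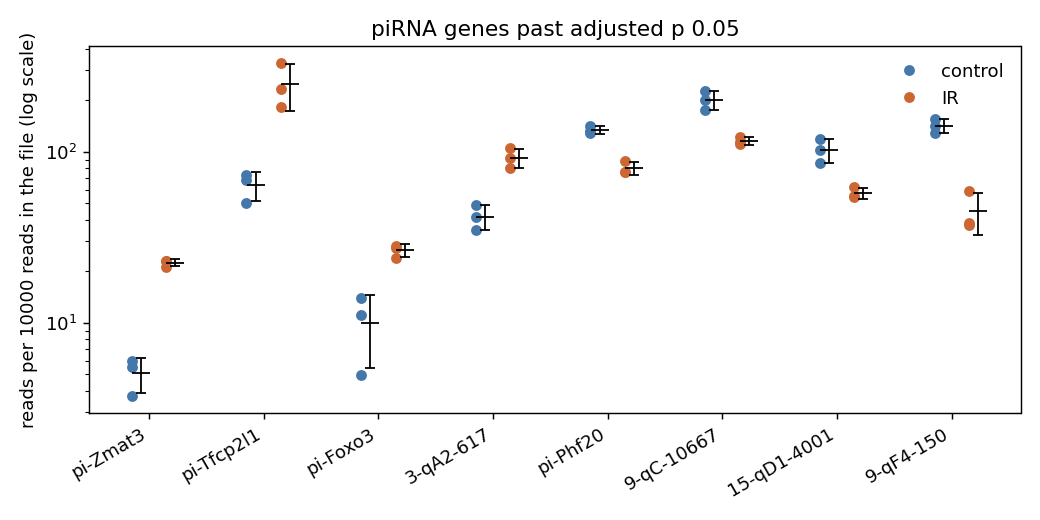
Reads per 10000 reads in the file (log scale) for the 8 piRNA genes past adjusted p 0.05, with points for the 3 control and 3 IR libraries and bars for the mean and SD of each group. The IR points lie above the control points for 4 genes, pi-Zmat3 among them, and below them for the other 4.

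The loci with the most reads did not pass, apart from pi-Tfcp2l1 and 9-qC-10667. pi-D730040F13Rik, at the gene now called Tmem245 (chromosome 4, 56866923 to 56947437, minus strand), took 370319 ± 26513 CPM in control and 343467 ± 15572 in IR (log2 fold change -0.11, SE 0.11, adjusted p = 0.605, edgeR). Structured RNA gave 78.1% of its reads, and without such reads its log2 fold change was -0.19 and past the threshold (adjusted p = 0.0437, range over alternatives 0.00236 to 0.896). On reads of 24 to 32 nt it was 0.12. The others of the 10 highest, 14-qA3-2286, 14-qA3-19970, 7-qF3-3125, pi-D10Wsu102e, 7-qD1-19431, 2-qE1-35981 and 5-qG3-23659, had log2 fold changes from -0.67 to 0.45. 14-qA3-2286, at the upper end, was at 1.19 (SE 0.35, adjusted p = 0.0845, edgeR) on reads of 24 to 32 nt and at 0.047 (SE 0.19, adjusted p = 0.936, edgeR) without control replicate 3. 14-qA3-19970, at the lower end, had an adjusted p of 0.226, which was 0.000938 without control replicate 3 and 0.00694 without a filter (edgeR). With the replicate block and without structured RNAs it was 5.81e-05, the lowest of its range (5.81e-05 to 0.550). pi-D10Wsu102e passed only with the replicate block and without structured RNAs (adjusted p = 0.0356, range 0.0356 to 0.862).

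Genes of the fixed lists were rarely among the piRNA genes. Of 30 p53 targets, Zmat3 had reads and rose. Of 44 histone genes, Hist1h1a (chromosome 13, 23763666 to 23764406, plus strand) had reads, with a log2 fold change of -0.53 (SE 0.28, adjusted p = 0.281, edgeR). Adjusted over the list alone, the edgeR p was 7.26e-05 for pi-Zmat3 and 0.0869 for pi-Hist1h1a, as each list has a single tested locus. The lists of DNA repair, piRNA pathway, germ cell and pluripotency, meiosis, apoptosis, Sertoli, Leydig, endothelial and blood genes had 0 loci with reads. Only reads on cluster transcripts were available, so a gene without such a cluster could not have reads here. The lack of reads therefore says nothing about the expression of these genes or the purity of the cells.

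The second comparison counted each distinct sequence, of which 124 were tested: 6 were higher and 4 lower in IR. With the total of the file as library size, which moved the median log2 fold change by -0.25, 4 were higher and 5 lower. Of the 6 that rose, 4 had the sequence of U1, the small nuclear RNA that recognises 5' splice sites, around its binding site for Sm proteins. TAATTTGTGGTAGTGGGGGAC numbered 1, 3 and 3 reads in the control and 79, 45 and 29 in the IR libraries (log2 fold change 4.52, SE 0.49, adjusted p = 0.000151, edgeR). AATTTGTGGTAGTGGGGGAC rose from 2 reads in the 3 control libraries to 72 in IR (adjusted p = 0.000983, edgeR), a rate ratio of 34.3 (exact 95% interval 9.16 to 289). Both control reads were in control replicate 1, and without it the rate in IR was 14.9 times the highest rate that a control count of 0 allows. Summed by first 20 nt, its log2 fold change was 3.52 (SE 0.60) in place of 5.08 (SE 0.71). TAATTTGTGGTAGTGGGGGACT rose by 2.61 on the log2 scale (SE 0.52, adjusted p = 0.00957, edgeR). These lie at positions 6014 to 6035 of a pi-Tfcp2l1 transcript and begin at nucleotide 124 or 125 of U1 (Rnu1a1, chromosome 11, 87422867 to 87423030, plus strand).

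Over all U1 reads, those that begin at nucleotide 124 numbered 24 in the control and 262 in the IR libraries. Reads that begin at nucleotide 125 numbered 11 and 118, those at nucleotide 123 numbered 2 and 57, and those at nucleotide 126 numbered 59 and 168. At nucleotide 10 the numbers were 30 and 39. These counts by first nucleotide of U1 were made after the data were seen and were not tested singly.

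**Figure D2:**
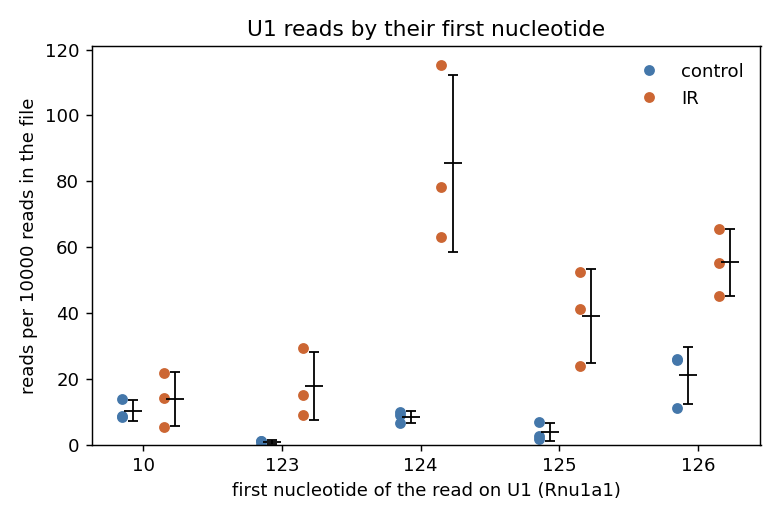
Reads per 10000 reads in the file by the first nucleotide of the read on U1, for the 5 commonest positions, with points for each library and bars for mean and SD (n = 3 per group). At nucleotides 123 to 126 every IR library lies above every control library, and at nucleotide 10 the groups overlap.

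Other sequences past the threshold matched microRNA, small nuclear RNA or tRNA, or no annotated transcript. TCGAGGAGCTCACAGTCTAGT, which matches the microRNA gene Mir151, rose from 1, 5 and 3 to 24, 40 and 11 reads (log2 fold change 3.12, SE 0.54, adjusted p = 0.00351, edgeR). TTAAATGGATTTTTGGAAGT, matching an annotated U2 gene, rose by 1.35 (SE 0.33, adjusted p = 0.0258, edgeR), while the sum of the U2 reads on cluster transcripts did not pass. The tRNA-Lys fragment TCTGAGGGTCCAGGGTTCAAGT fell by 2.19 on the log2 scale (SE 0.37, adjusted p = 0.00351, edgeR). CCTTTAATCTCGACACTTGGA, AGGCAGAGGCTGGCGGATCTCC and CGCCACTACTGCCCGGCTCC, which matched no annotated transcript, fell by 1.65 (SE 0.42), 2.80 (SE 0.66) and 2.42 (SE 0.61), each with adjusted p = 0.0258 (edgeR). Of the most abundant sequences, TGCAGATGATGTGACAGAAT and TGCAGATGATGTGACAGAATA of the small nucleolar RNA Gm23969 (chromosome 2, 26911261 to 26911334, plus strand) had adjusted p of 0.494 and 0.210 (edgeR). GGGGATGTAGCTCAGTGGTAGAGC of tRNA-Ala and TCGATTCCCGGCCAACGCACCA of tRNA-Gly had 0.625 and 0.156, and none of these 4 passed.

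Without control replicate 3 several of these calls were lost. TCGAGGAGCTCACAGTCTAGT then had an adjusted p of 0.0517 (edgeR; range over alternatives 0.000244 to 0.0517), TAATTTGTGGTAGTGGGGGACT 0.0799 (range 0.000239 to 0.0799) and AGGCAGAGGCTGGCGGATCTCC 0.104 (range 0.000239 to 0.104). AGGCAGAGGCTGGCGGATCTCC had 1, 9 and 0 reads in the IR libraries, so the size of its fall rested on IR replicate 2, without which 1 IR read against 79 in control gave a rate ratio of 0.0192 (exact 95% interval 0.000480 to 0.110). For CGCCACTACTGCCCGGCTCC, the 3 IR reads left without IR replicate 2 gave 0.0928 (exact 95% interval 0.0185 to 0.288). TTAAATGGATTTTTGGAAGT was lost without control replicate 2 (0.143), control replicate 3 (0.121) or IR replicate 1 (0.0703), with the file total as library size (0.0548) and without a filter (0.432, range 0.00734 to 0.432). CGCCACTACTGCCCGGCTCC was lost without control replicate 2 (0.0660), control replicate 3 (0.120) or IR replicate 1 (0.0612) and without a filter (0.0550, range 0.00734 to 0.120). CCTTTAATCTCGACACTTGGA was lost without control replicate 3 (0.0630), IR replicate 1 (0.145) or IR replicate 2 (0.120) and without a filter (0.102, range 0.00229 to 0.145). The count of 10 sequences became 16 without control replicate 1, 4 without control replicate 3 and 21 without IR replicate 3.

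The third comparison concerned read size, with 24 to 32 nt taken as the size of piRNAs. Size alone does not tell piRNAs from fragments of structured RNA. The leading sequence of pi-D730040F13Rik, with 409 reads, had 28 nt and matched 4.5SH RNA. Of 29 lengths tested, reads of 20 nt were higher in IR, by 1.25-fold (log2 fold change 0.32, SE 0.066, adjusted p = 0.000123, edgeR), and no other length passed. Reads of 20 nt are the most abundant length. Simulated 2-fold and 4-fold changes placed on 4 of the 29 lengths, abundant ones included, gave 36.1% false calls. No simulated change was as small as 1.25-fold, so the rate of false calls beside such a change is not known. DESeq2 called 0 lengths, with 1 at an unadjusted p under 0.05, and gave reads of 20 nt an adjusted p of 0.375 (range over alternatives 2.94e-06 to 0.375). The call was also lost without control replicate 2 (0.105), control replicate 3 (0.237) or IR replicate 2 (0.193), and without IR replicate 3 there were 2 calls. The share of 24 to 32 nt reads was 38.6% ± 1.28 in control and 35.6% ± 0.811 in IR, with every IR library below every control library (exact permutation p = 0.1, the smallest possible with 3 against 3). On reads of 24 to 32 nt alone, edgeR called 0 of 28 loci and 0 of 48 sequences, with 5 and 8 at an unadjusted p under 0.05.

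**Figure D3:**
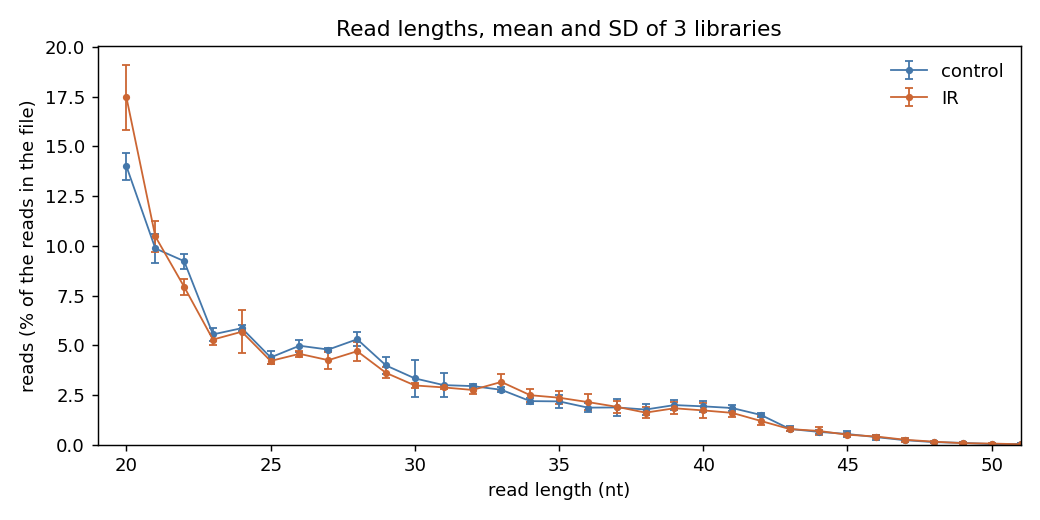
Share of the reads in the file (%) at each read length from 20 to 50 nt, as mean and SD of the 3 libraries per group. The IR libraries have a higher share at 20 nt (1.25-fold), and reads of 24 to 32 nt make up 38.6% of control and 35.6% of IR reads.

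Marks of piRNA biogenesis were compared within reads of 24 to 32 nt. U at position 1, the first-base preference of primary piRNAs, was found in 39.3%, 32.9% and 30.5% of the control and 29.8%, 30.9% and 27.3% of the IR reads (exact permutation p = 0.2). The difference in first U was -4.87 percentage points, and -2.34 without control replicate 1. On reads of 26 to 31 nt it was -7.76, and on reads of 1 piRNA gene -6.24, with every IR library below every control library in both (exact permutation p = 0.1, the smallest possible). With distinct sequences counted once it was -3.51 (exact permutation p = 0.5), and without structured RNAs -3.69 (exact permutation p = 0.6). Without control replicate 1 these 4 differences were -4.91 on reads of 26 to 31 nt, -3.42 on reads of 1 piRNA gene, 0.38 with distinct sequences counted once and -0.0025 without structured RNAs, settings chosen after the data were seen. A at position 10, the mark of ping-pong secondary piRNAs, was found in 21.8% ± 1.88 of control and 22.5% ± 0.580 of IR reads (exact permutation p = 0.7). This difference was 1.53 percentage points with distinct sequences counted once, with every IR library above every control library (exact permutation p = 0.1). On reads of 1 piRNA gene it was 0.029 (exact permutation p = 0.9), and without structured RNAs 1.21 (exact permutation p = 0.3). Of opposite-strand pairs, 2.60% ± 0.334 in control and 1.85% ± 0.886 in IR overlapped by 10 nt (exact permutation p = 0.3). The z-score of that overlap was below 0 in every library, from -1.09 to -0.28, so no ping-pong excess was detectable on reads of 24 to 32 nt at this depth. On reads of 26 to 31 nt the share was 6.99%, 2.53% and 0.88% in control and 0.50%, 0.57% and 4.66% in IR (exact permutation p = 0.5). No z-score was computed for that size.

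Repeated and distinct sequences were compared next. Reads on more than 1 piRNA gene made up 21.8% ± 1.35 of control and 22.2% ± 2.16 of IR reads (exact permutation p = 0.9). On reads of 24 to 32 nt they made up 22.2% ± 1.02 and 25.3% ± 2.87 (exact permutation p = 0.2). With distinct sequences counted once they made up 26.6% ± 1.35 and 28.5% ± 0.906 (exact permutation p = 0.2). The 10 most abundant sequences made up 9.80% ± 1.92 and 8.78% ± 1.12 (exact permutation p = 0.6). At 7788 reads, the libraries held 4304 ± 263 and 4598 ± 38.9 distinct sequences (exact permutation p = 0.1). Thinned to equal depth on reads of 1 piRNA gene, they held 3085 ± 201 and 3231 ± 30.9 (exact permutation p = 0.3). On reads of 24 to 32 nt they held 1607 ± 165 and 1669 ± 49.0 (exact permutation p = 0.6). Of the 23 listed small RNAs, 3 were seen. miR-202-5p had 1 read in control replicate 1 and 3 in IR replicate 1, miR-294-3p had 1 in IR replicate 2, and the 5' fragment of tRNA-Glu had 1 and 2 in IR replicates 2 and 3. The listed classes together made up 0.00331% ± 0.00574 of control and 0.0233% ± 0.00487 of IR reads (exact permutation p = 0.1). The listed starts of ribosomal RNA and Y RNA had 0 reads, which allows up to 0.0385% of the reads on cluster transcripts in the library with the fewest. Because reads elsewhere were not available, this sets no limit on these RNAs in the whole library.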

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

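The tests of structured reads, of U2 and U6, of U1 among reads of 20 to 22 nt and of reads matching Zmat3 alone, and those on control replicate 1, were chosen after the results were seen. IR replicate 2 held 78 reads longer than 57 nt, beyond the selected 18 to 50 nt, against 2, 0 and 1 in the control libraries and 2 and 3 in the other IR libraries. They were 0.692% of its reads, in 76 distinct sequences on 34 piRNA genes, 74 of which lay on the minus strand of the transcripts alone.

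Reads of U1 and of pi-Tfcp2l1 were higher in IR. Without reads of structured RNAs the log2 fold change of pi-Tfcp2l1 was 0.62 (SE 0.34) in place of 1.89 (SE 0.27), so the smaller fold ended the call, and U1 reads may account for most of it. An equal rise of the U1, U2 and U6 reads seen here is argued against by U2, at -0.16 (SE 0.20), and U6, at -0.58 (SE 0.35), against 2.21 (SE 0.33) for U1. These values sum only reads that map to cluster transcripts, which may cover unlike parts of each RNA. They therefore cannot tell whether the whole RNAs rose alike. The U2 fragment of 20 nt named above rose by 1.35 (SE 0.33, adjusted p = 0.0258, edgeR), a call lost without some single libraries. A change shared by certain fragments of U1 and U2 therefore stays open. More 20 to 22 nt reads of every kind are argued against too, since U1 rose 4.55-fold among reads of that size (exact 95% interval 3.75 to 5.54). U1 reads of 23 nt or longer, 1 in control and 9 in IR, had a rate ratio of 8.90 (interval 1.23 to 390). That ratio leaves open whether shorter reads in IR play a part. Both intervals pool the reads of a group and leave out the spread between libraries. Per library, U1 took 0.277% to 0.566% of all reads in control and 1.56% to 2.84% in IR. 7SL also rose (2.03, SE 0.33), so the rise was not limited to U1, and neither an effect of irradiation nor a source common to both RNAs was tested.

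Reads of pi-Zmat3 were higher in IR. Reads shared with other annotated transcripts are argued against as the whole cause, since reads that matched Zmat3 exactly in sense, and no transcript of another gene, rose 7.81-fold (exact 95% interval 3.09 to 25.3), from 5 to 41. That interval pools the reads of a group and leaves out the spread between libraries. Copies outside annotated transcripts, such as repeats, were not searched for, because no genome sequence was used here, and stay open. Of the 25 IR reads of 24 to 32 nt, 28% began with U (exact 95% interval 12.1 to 49.4), which argues against a majority of first-U piRNAs. Among all IR reads of that size 27.3% to 30.9% per library began with U, so this share does not set pi-Zmat3 apart from other loci. Fragments of a more abundant Zmat3 mRNA may explain the rise, a hypothesis that was not tested because mRNA was not analysed here.

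Control replicate 1 held 226 reads of 29 to 32 nt on 12 listed clusters active at the pachytene stage of meiosis, against 41 and 68 in the other control and 76, 55 and 46 in the IR libraries. Of these 226 reads, 74.3% began with U (exact 95% interval 68.1 to 79.9), against 20% to 36.6% in the other libraries. Among its 837 reads of 29 to 32 nt outside the list, 45.4% began with U, against 26.6% to 29.6% in the other libraries, so the excess of first U was not confined to the listed clusters. Greater depth is argued against, since these reads were 2.97 times those of IR replicate 1 and the ratio of all reads was 0.892. The U1 share of control replicate 1 was 0.566%, under the 1.56% of the lowest IR library. U1 was singled out because it differed between the labelled groups, this library included. Its share therefore cannot decide whether the library is mislabelled, and it does not bear on a library from outside this set. A trace of piRNAs of meiotic or later germ cells may explain the excess, although per the labels the cells were purified from male embryos. Whether such piRNAs came from the embryos at all, or from a library outside this set, was not tested. The cluster list was written from general knowledge after the excess was seen.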

How the results depend on the processing

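Settings without structured RNAs, with 1 mapped place, without pi-D730040F13Rik or on 20 to 28 nt, the source RNAs, the splits and first U in other read classes without control replicate 1 were chosen after the data were seen. On 24 to 32 nt reads edgeR called 0 loci and 0 sequences (5 and 8 at an unadjusted p under 0.05), with fewer features tested. Reads with 1 mapped place gave 5 loci of 56 tested, and sums by the first 20 nt gave 20 sequences. DESeq2 gave 0 lengths (1 at an unadjusted p under 0.05) and no filter gave 3. Leaving out each library gave 3 to 15 loci, 4 to 21 sequences, 0 to 2 lengths and 6 to 13 source RNAs. Apart from the smaller number of features or libraries, the cause was not tested.

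Of 452 refits of named loci, sequences and lengths, 382 kept direction and side of the threshold, 52 lost the call, 6 gained it and 12 reversed. On 24 to 32 nt reads 15-qD1-4001 was at 0.16 and pi-D730040F13Rik at 0.12. 5-qG3-23659, at -0.013 with all libraries, was at 0.079 on 24 to 32 nt, 0.83 on 20 to 28 nt, 0.11 without structured RNAs and 0.16 with the block added. Without each library, 5-qG3-23659 ranged from -0.17 to 0.17, 7-qD1-19431 from -0.15 to 0.21, and GGGGATGTAGCTCAGTGGTAGAGC from -0.31 to 0.87. Leaving out TMM moved 5-qG3-23659 to 0.065 and 4.5SH to 0.022, about the shift of the median locus (0.078) and source RNA (0.066), so these sign changes follow from the scaling. tRNA-Ala was at -0.042 without a filter, -0.092 with the block and -0.53 to 0.33 without each library. The log2 total difference was -0.054 on 24 to 32 nt reads and -0.066 to 0.24 without each library. The difference in A at position 10 ranged from -0.25 to 1.61 and that in the multi-gene share from -0.60 to 1.56 percentage points without each library. The difference in first U was 0.38 with distinct sequences counted once and without control replicate 1. Apart from the scaling, the cause of these reversals was not tested. On reads of 1 piRNA gene the ping-pong share was 0 in each of the 6 libraries, so there was nothing to compare.

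Same-numbered libraries had correlations of -0.167, 0.109 and 0.123 between their deviations, and 2 of 6 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate block 7 loci, 10 sequences, 1 length and 11 source RNAs passed. For composition measures, exact sign-flip tests over 3 pairs cannot go below p = 0.25. Merging within 1 kb or 50 kb and the gene list tests were not run.

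The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 8 loci, 10 sequences, 1 length and 11 source RNAs, and the highest other split 1, 0, 0 and 0. In each case 1 split, the real one, gave as many calls.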

Other observations

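Reads were also counted by source RNA, a test chosen after the data were seen, and 11 of 114 passed the threshold, 6 higher and 5 lower in IR. Reads of 7SL, the RNA of the signal recognition particle (Rn7s1, chromosome 12, 69159295 to 69159594, plus strand), rose 4.07-fold, from 10, 15 and 9 to 54, 54 and 46 (log2 fold change 2.03, SE 0.33, adjusted p = 0.00355, edgeR). U1 rose by 2.21 (SE 0.33) and Mir151 by 1.94 (SE 0.51). Fragments of tRNA-Lys fell by 2.16 (SE 0.35) and those of tRNA-Gly by 1.24 (SE 0.21), with adjusted p of 0.00355 and 0.00367 (edgeR). Reads matching Mir9-1 fell by 1.11 (SE 0.22, adjusted p = 0.0110, edgeR). Their counts equalled those of a single 20-nt sequence in every library. In the comparison of sequences that sequence did not pass, with a log2 fold change of -0.77 (SE 0.32, adjusted p = 0.176, edgeR). The Mir9-1 call therefore depended on which comparison the same counts entered. The others past the threshold were 9-qF4-150, pi-Zmat3, 3-qA2-617, pi-Phf20 and pi-Foxo3. tRNA-Ala, 4.5SH, U2, U6 and Gm23969 did not pass, with log2 fold changes of 0.027, -0.046, -0.16, -0.58 and 0.45. Those of 4.5SH and tRNA-Ala changed sign with the scaling or filter.

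Calls by source RNA were lost when some libraries were left out. Mir9-1 lost its call without IR replicate 1 (adjusted p = 0.0715, edgeR) or IR replicate 2 (0.0836), in a range from 0.00129 to 0.0836 over its alternatives. Mir151 lost it without control replicate 1 (0.0577), IR replicate 1 (0.0987) or IR replicate 2 (0.196), in a range from 0.000177 to 0.196. In this count 3-qA2-617 lost its call without control replicate 2 (0.0853), IR replicate 1 (0.0755) or IR replicate 2 (0.0561), and pi-Phf20 without any 1 of the 6 libraries (0.0676 to 0.107). pi-Foxo3 lost it with the replicate block (0.0824) and without control replicate 2 (0.0873), IR replicate 1 (0.0987), IR replicate 2 (0.150) or IR replicate 3 (0.114). The count of 11 source RNAs became 6 without IR replicate 1 and 6 without IR replicate 2. U1, 7SL, tRNA-Lys, tRNA-Gly, pi-Zmat3 and 9-qF4-150 passed in each of their 10 alternatives.

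In pi-Foxo3, 15 of 34 IR reads of 24 to 32 nt began with U, against 1 of 12 control reads, a difference that was not tested. Of its reads, 47 in IR and 17 in control matched Foxo3 transcripts exactly.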
